A study of Drosophila melanogaster with 58 samples.

How the data were processed

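Poly(A)-spanning reads from 58 libraries were analysed, which the labels place in 29 groups of 2 biological duplicates over 10 tissues of Oregon R flies. Per the file headers and the labels, the deposited files hold other values than counts: each line is 1 read placed by Bowtie, whose version is not stated, at a unique position of genome build dm3, with its start and end and no counts column. Per the labels' design, these are reads with at least 10 A at an end that were left unmapped until the run of A was trimmed. There were 116 files, 1 per strand and library. Everything below was computed here from the starts and ends.

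The poly(A) position of a read was its end on the plus strand and its start on the minus strand. The 111159 distinct positions were joined within 25 nt on a strand, and groups of at least 10 reads over all libraries were kept as sites, giving 6623 sites with a median width of 11 nt that held 92.1% of the reads. Reads per site and library were then counted. Levels are a library's reads at a site as a percent of its reads at nuclear sites; this unit was chosen after scaled levels had been seen, and the sites picked by the naming rule for the text, 47 in 65 tests, were the same with either. Of these tests, 2 in imaginal discs are not printed, and 7 further called sites of heads that the text singles out are not among them and were not followed under the alternatives.

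Libraries held 2178 to 122588 reads, with a median of 16592.5, and 6 held fewer than 5000, so a site absent from such a library can hold a level that deeper libraries would show. Per the file headers, 12 libraries came from a smaller flow cell with aligned lengths of 21 to 67 nt, and 46 from a larger one with 21 to 91 nt. Reads with distinct starts and ends made up 13.4% to 70.9% of a library's reads, with a median of 34.6%. Copies made by PCR were kept and were counted once as an alternative.

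The tests of sites used a negative-binomial log-linear model coded from its formula. It had 30 coefficients, for the 29 groups and the flow cell, and TMM scaling factors (0.385 to 3.50, trimming 30% of log ratios and 5% of abundances). Dispersions were set in 5 abundance classes and ran from 0.296 to 0.490. Quasi-dispersions from deviances were moderated by a method modelled on squeezeVar of limma, coded here with a quadratic trend on log reads (prior degrees of freedom 13.0). F tests were adjusted by the method of Benjamini and Hochberg at 0.05. Sites needed the equivalent of 10 reads at the median depth in 2 libraries and 15 reads in all, which left 1241 nuclear sites. All adjusted p-values of sites in the report come from this model. The fit pooled the spread over all 58 libraries, and where leaving out a library left 1 in a group, that library was assumed to vary like the others. Where libraries with 0 reads leave group and lane or flow cell free to trade against each other, the test says nothing, since its p depends on where the fit stops. This held for 0 of these 65 tests and 1 of 2202 calls, rises and falls of all comparisons together, with the flow cell term. With lane terms it held for 15 of the 65 and 4 of 998 calls.

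The planned edgeR test was not used for the report. The deposited files hold no counts column, which was read as ruling out packages for counts under the rules set for the work, although reads per site can be counted and the test could be run on them. An exploratory run of it on reads per site was made before the main test was chosen, and its calls were seen. It called as many sites as the model used or more in every comparison, including some in 3 comparisons in which the model called none, and it is not in the results. In most comparisons it called fewer sites than limma voom. It was not among the 9 tests compared below. The main test was chosen after the data were examined, and the counts of the tests tried had been seen. The criterion was the share of false calls in simulated data, with 200 of 1241 sites changed 4-fold in 4 draws of each of 25 comparisons, and 9 tests were compared. The model gave 241 false calls of 4785 (5.04%), its version with Pearson dispersions 15.6%, limma voom 9.17%, limma voom with a prior scaled to depth 20.1% and limma trend 14.1%. Simulated reads were themselves negative-binomial, which favours a model of that kind, and the chosen test also gave the fewest calls on simulated data. The comparisons, the flow cell covariate and the alternatives not named below as added were fixed before the data were examined, for genes. Sites took the place of genes afterwards, and the level unit of the naming rule was chosen then too.

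Sites named by rule were, for each comparison, the 10 with the largest rise and the 10 with the largest fall among those past 0.05 with a level of at least 0.01% in the higher arm and every library of that arm above every library of the other. For a tissue against the others the 3 largest rises past 0.05 with that level were named, whether or not every library lay apart, and for distal runs 3 in each direction; the text gives up to 3 in each direction, by rank, except for salivary glands, where 4 rises were picked from the named ones, and for runs, where part of the named ones are given. Each tissue was compared with the mean of the other 9, each tissue being the mean of its groups.

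Sites less than 2000 nt apart on a strand formed a run, and sites with a mean share of at least 5% over tissues with at least 10 reads were kept. In 787 runs at least 2 sites were kept; 659 of them had 2, and the median distance between sites was 352 nt. Runs with at least 20 reads in the tissue were tested with a quasi-binomial model of distal against other reads, in which reads were weighted by Williams' method for a correlation between reads of 0.247 to 0.313. Of 6 versions tried on simulated runs with a changed log odds of 2, this one gave 19 false calls of 235 (8.09%) and recovered 34.2% of 632 changed runs. It did not have the lowest false share: the version with the larger of both dispersions gave 13 of 196 (6.63%) and recovered 29.0%, while weighing reads in full gave 35.7% to 45.9% false. The simulated runs pooled correlations between reads below and above the fitted 0.247 to 0.313, so these shares hold for no single correlation. The distal score of a library is the mean, over runs with at least 10 reads in it, of the distal share minus the run's mean over tissues with at least 20 reads. Scores and mitochondrial shares were compared by two-sided permutation of libraries, exact for tissues with 2 or 4 libraries and with 100000 resamples for the others, and adjusted over 10 tissues. The limit up to which splits were counted in full was raised after the design was fixed.

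Alternatives changed 1 choice at a time: TMMwsp scaling, no filter, no flow cell term, PCR copies counted once, mitochondrial reads kept, only the compared groups, sites joined within 10 or 50 nt, a smallest share of 10%, at least 20 reads per run, limma on log2 odds, and each library left out. Pearson dispersions, the limma tests of sites, reads weighed in full, the larger flow cell alone, the removal of 5 shallow libraries, terms for the 5 lanes in place of the flow cell term, the alternatives of the tests on lists of sites, and leaving out libraries for the scores and mitochondrial shares were added after the data were examined. For distal runs, scores and mitochondrial shares, libraries were left out only in tissues with 2 or 4 libraries. Heads, digestive system, carcass and fat were thus not covered. Other splits of the libraries, 100 for each result tested, were drawn with the same model. Gene lists, the share of sites with an AATAAA signal, internal priming and tests of genes were left out, since no genome or annotation of dm3 was used here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.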

Results

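The libraries came from dissected tissues of Drosophila melanogaster, the fruit fly, of the wild-type strain Oregon R. Each read spanned the junction between the end of a transcript and its poly(A) tail, the run of adenosines added where the transcript is cleaved, so a read marks 1 poly(A) site. The 58 libraries fell into 29 groups of 2 biological duplicates each and covered 10 tissues. Heads made up 9 groups, namely virgin females, mated females and mated males at days 1, 4 and 20 after eclosion, the emergence of the adult fly. The digestive system and the carcass, the part of the body left after dissection, had 4 groups each, from larvae and from adults of mixed sex at days 1, 4 and 20. Fat had 3 groups, from larvae, from white prepupae (the stage at which the larva has just formed its pupal case) and from pupae 2 days later. Salivary glands of larvae and white prepupae, the central nervous system (CNS) of larvae and of pupae 2 days after the white prepupa, and day 4 ovaries of virgin and mated females made up 2 groups each. Testes and accessory glands of mated males at day 4, and imaginal discs of larvae, the pouches of cells that give rise to adult structures, had 1 group each.

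Libraries held 2178 to 122588 reads, with a median of 16592.5 and 1384937 in all. Reads gathered at 6623 poly(A) sites, of which 6606 were nuclear and 17 mitochondrial, and 1241 nuclear sites held enough reads to be tested. A site is named by its chromosome, its most used position and its strand on genome build dm3, and its level is the percent of a library's nuclear site reads, given as mean ± SD over n libraries. No annotation of dm3 was used here, so no site is assigned to a gene, exon or untranslated region. Where every library of a group had 0 reads at a site, the fold is a lower bound set against 3 reads over that group. Such bounds, and any interval on a share of reads, cover counting error only. The 3 reads are set against the pooled depth of the group, so deep libraries weigh most. The model's fold adds prior reads and was smaller than some of these bounds, as given below.

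A few sites took most of the reads in some tissues. The 10 most used sites of a library held 18.9% to 78.1% of its reads in heads, 44.6% to 77.7% in carcass and 47.7% to 67.3% in salivary glands, against 15.1% to 21.6% in imaginal discs and 20.1% to 22.9% in testes. The library closest to each of the 58 was from the same tissue for all 58 and from the same group for 40. The levels of the 2 libraries of a group correlated across sites at 0.455 to 0.974 with a median of 0.795, where sites are not independent replicates.

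The first comparison asked which poly(A) sites differed between the heads of mated males and mated females, averaged over the 3 ages. The site X:9949531+ took 52.4% ± 14.2 (n = 6) of the reads in mated female heads and 0.581% ± 0.645 (n = 6) in mated male heads, a log2 difference of -8.78 ± 0.72 (SE, adjusted p = 8.46e-09). X:13655200+ took 6.24% ± 9.82 in females and 0.0719% ± 0.0596 in males (log2 -7.28, adjusted p = 8.10e-09). X:9945057-, on the opposite strand, took 0.808% ± 0.643 in females and 0.0145% ± 0.0167 in males (log2 -6.41, adjusted p = 6.88e-06). Of 1241 sites, 1 was higher in male heads and 5 were higher in female heads. The other 3, which the naming rule left out and which were singled out after their values were seen, were X:3752938-, with 0.115% in males and 0.000677%, from 1 read, in females, 2R:15331023+, with 0.284% and 0.471%, and 3L:3221113-, with 0.433% and 0.648%. At each of them male and female libraries overlapped. Their folds in the model were 8.56, 4.82 and 3.70, unlike the ratios of these means. Levels are shares of all nuclear site reads, so the large share of X:9949531+ in female heads lowers their levels at other sites. A second scaling of the libraries (TMMwsp) called 5 sites, 0 higher and 5 lower in males, and other settings called 3 (no filter on low reads) to 35 (limma voom with a depth-scaled prior). The split depended on the test: limma voom called 10 higher and 10 lower in males. Terms for the 5 sequencing lanes in place of the flow cell term gave 6 sites again, 1 higher and 5 lower. The count was 3, all higher in females, when either day 4 library of either sex, either day 1 male library, mated female day 1 replicate 1 or mated female day 20 replicate 1 was left out. One library, mated female day 20 replicate 2, held 26.2% of its reads at X:13655200+, against 1.45% to 3.74% in the other 5 mated female heads, and virgin heads of day 20 were also high, as given with ageing.

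**Figure D1:**
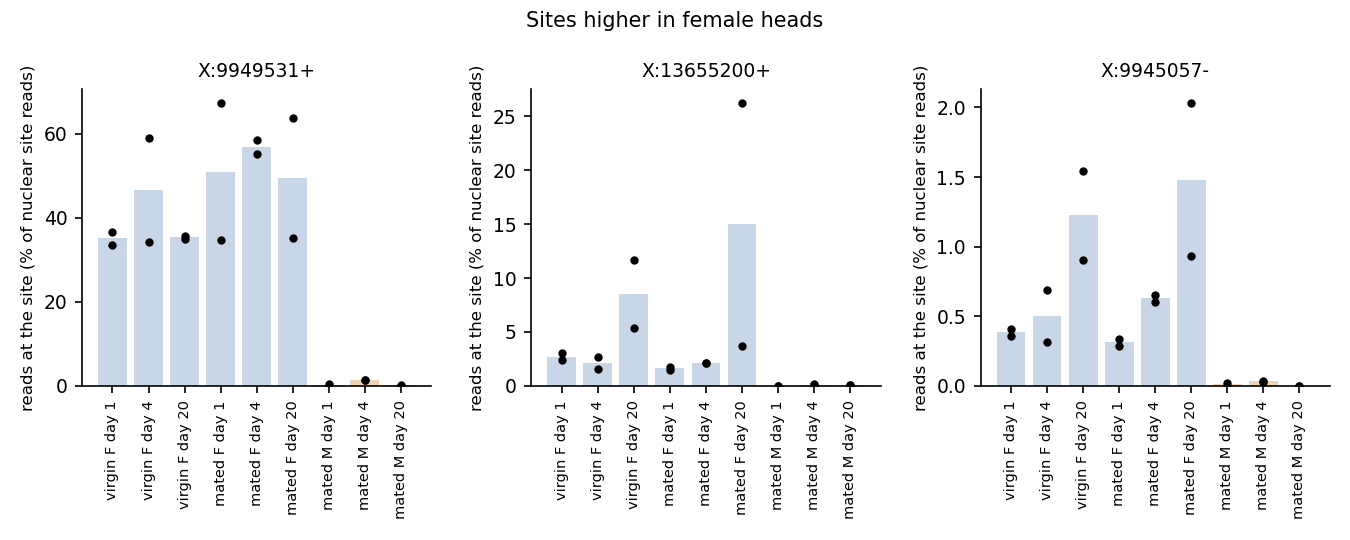
Reads at X:9949531+, X:13655200+ and X:9945057- in each head library, as a percent of its nuclear site reads, for virgin females, mated females and mated males at days 1, 4 and 20. Bars are means of 2 libraries and points are libraries; male heads hold at most 1.45% at X:9949531+, and female heads at least 33.6%.

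Mated and virgin female heads were compared over the same ages. X:9949531+ led in both, with 33.6% to 59.1% of the reads in the 6 virgin libraries and 34.6% to 67.3% in the 6 mated libraries. At X:13655200+ the virgin libraries held 1.56% to 11.7% and the mated ones 1.45% to 26.2%. The negative-binomial model called 0 of 1241 sites, with 70 at an unadjusted p under 0.05, and limma voom called 3, limma voom with a depth-scaled prior 9 and limma trend 4. In simulated data for this comparison, over 1241 sites, the model recovered 16.9% of sites changed 4-fold.

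Ageing was examined as day 20 against day 1, averaged over the 3 kinds of head. The site 2L:7743920- took 0.351% ± 0.122 (n = 6) of the reads at day 1, from 195 reads, and 0 reads at day 20 (n = 6). The bound was 182-fold lower, set against day 20 libraries of 2178 to 85364 reads. The model's fold for this site was smaller (log2 -5.74, adjusted p = 0.00476). It was 1 of 5 sites called, 1 higher and 4 lower at day 20. The other 4, named after their values were seen, were 2R:19949375-, whose mean rose from 0.0864% to 0.362%, 2R:5937571+, whose mean fell from 5.08% to 3.02%, 2L:16788766+, from 0.119% to 0.0257%, and X:17116999-, from 0.142% to 0.00441%. At each of them libraries of the compared ages overlapped. At 2R:5937571+ libraries ran from 0.144% to 11.5% at day 20 and from 3.11% to 7.37% at day 1. Its fold was 3.64 in the model and 1.69 between these means. Under other settings the count ran from 0 (lane terms) to 103 (limma trend), with 14 under TMMwsp, 14 without a flow cell term and 10 on the larger flow cell alone. The direction was not stable either: 23 were higher and 13 lower with only the compared groups, 6 and 4 on the larger flow cell alone, and 3 and 2 without the shallow libraries. Day 1 heads were sequenced in lanes 1 (3 libraries) and 4 (3), and day 20 heads in lanes 2 (5) and 8 (1). Among head groups, only mated males of day 20 (lanes 2 and 8) and virgins of day 4 (lanes 4 and 8) linked lane 2 to the lanes of day 1. Groups of other tissues in the same fit linked these lanes too, such as carcass of day 4 (lanes 2 and 8) and of day 1 (lanes 1 and 8). With lane terms 2L:7743920- stood at log2 -5.50 ± 1.64 (SE, adjusted p = 0.171), against -5.74 ± 1.01 before, so the fold held and the call ended with the wider error. Picked out after their values were seen, the 4 day 20 female heads, all in lane 2, lay above the 8 younger ones at X:13655200+ (3.74% to 26.2% against 1.45% to 3.03%) and X:9945057- (0.907% to 2.03% against 0.288% to 0.687%). Over all heads neither site was called, with log2 2.46 (adjusted p = 0.0662) at X:13655200+ and 1.13 (adjusted p = 1.00) at X:9945057-. It was 0 without mated male day 20 replicate 2, 10 without mated female day 20 replicate 1, 3 without mated male day 1 replicate 1, 2 without mated female day 1 replicate 1 or virgin day 1 replicate 2, and 1 without virgin day 1 replicate 1, virgin day 20 replicate 2, mated female day 20 replicate 2, mated female day 1 replicate 2 or mated male day 1 replicate 2. Whether the difference between the sexes itself changed from day 1 to day 20 was tested as an interaction: 0 of 1241 sites passed, with 80 at an unadjusted p under 0.05, and limma voom called 0, limma voom with a depth-scaled prior 31 and limma trend 12. With groups on 1 side of the interaction changed 4-fold in simulated data, the model recovered 2.25% of changed sites, so most would have been missed.

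Testes and ovaries of day 4 adults were compared directly. In testes 2L:18009694+ took 3.66% ± 1.55 (n = 2) of the reads, 3R:3190881- 2.80% ± 1.75 and 3L:10633240+ 2.19% ± 0.433. All 3 had 0 reads in the 4 ovary libraries, and were at least 403-fold, 309-fold and 241-fold higher in testes (adjusted p = 9.56e-06, 0.000142 and 0.000142). In ovaries 2L:5959699- took 7.30% ± 4.34 (n = 4), against 2 reads in testes, 2L:5957628+ took 1.41% ± 0.988, against 1 read, and X:7982896- took 0.892% ± 0.704, against 3 reads. The model called 151 of 1241 sites, 146 higher in testes, of which 122 had 0 reads in ovaries, and 5 higher in ovaries. The sites named by rule on the testis side include 3R:21656441- and 3L:16748820+, which were also the leading sites of accessory glands. In simulated data for this comparison, over 1241 sites, 2 of 16 calls (12.5%) were false. Other settings called 15 (no filter) to 359 (limma voom with a depth-scaled prior), and 67 sites passed without the shallow libraries and 19 with lane terms. The lean towards testes was weaker in some of them: limma voom called 184 higher and 73 lower in testes (71.6% higher against 96.7%), only the compared groups 75 and 31 (70.8%), and limma voom with a depth-scaled prior 248 and 111 (69.1%). Leaving out a library lowered the count to 39 or 63 (virgin ovary replicate 1 or 2), 14 or 35 (mated ovary replicate 1 or 2) and 93 or 66 (testis replicate 1 or 2).

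Mated and virgin ovaries were compared with each other at day 4. The leading ovary site, 2L:5959699-, is described with the other ovary sites. None of 1241 sites passed: the negative-binomial model called 0, with 8 at an unadjusted p under 0.05, limma voom called 0, and limma voom with a depth-scaled prior and limma trend 3 each. The model recovered 0.25% of sites changed 4-fold in simulated data for this comparison, over 1241 sites, so most changes of that size would have been missed.

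In the digestive system, larvae were compared with adults, averaged over days 1, 4 and 20. Larvae held 3.92% ± 2.46 (n = 2) of their reads at 3R:14519005-, where the 6 adult libraries had 2 reads (adjusted p = 4.82e-06). They also held 0.324% ± 0.0318 at 3L:20197717-, at 0 in adults. The bound was 237-fold higher in larvae, and the model's fold was smaller (log2 6.13). At 3L:8385477+ larvae held 0.326% ± 0.146, against 0.00382% ± 0.00323 in adults (log2 5.50). Adults (n = 6) held 1.18% ± 0.351 at 3R:161228+ and 0.459% ± 0.239 at 2R:8651252+, which were at 0 in larvae, at least 166-fold and 64.5-fold lower. At X:9949531+, the leading site of female heads, adults held 2.30% ± 0.835 and larvae 0.0228% ± 0.0322 (log2 -6.74, adjusted p = 0.00415). The model called 87 of 1241 sites, 49 higher and 38 lower in larvae. TMMwsp scaling gave 90 higher and 31 lower, 74.4% higher against 56.3%. Other tests gave the opposite lean, with 68 higher and 164 lower under limma voom (29.3%), 64 and 139 under limma trend, 44 and 137 under limma voom with a depth-scaled prior, and 105 and 129 with only the compared groups (44.9%), so the balance of rises and falls was not settled. Other settings called 6 (no filter) to 234 (only the compared groups), with 24 on the larger flow cell alone and 43 with lane terms, which decided nothing for 3R:14519005- and 3L:20197717-, where libraries with 0 reads left lane and group inseparable. The count fell to 3 without larva replicate 2, 19 without larva replicate 1, 56 or 46 without adult day 1 replicate 1 or 2, and 53 or 46 without day 20 replicate 1 or 2. Between days 20 and 1 of the adult digestive system the model called 0 of 1241 sites, with 64 at an unadjusted p under 0.05, while limma voom called 11, limma voom with a depth-scaled prior 14, limma trend 26 and the same model on only the compared groups 129 of 343 sites. For these days the model recovered 0.875% of sites changed 4-fold in simulated data, so most changes of that size would have been missed.

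Larval and adult carcasses differed most at sites of chromosome arm 2R. In larvae 2R:4325738+ took 30.3% ± 4.48 (n = 2) of the reads, 2R:4318143- 19.2% ± 9.52 and 2R:4321478- 9.06% ± 4.27. In adults (n = 6) the same sites held 0.0168% ± 0.0386, 0.0270% ± 0.0648 and 0.0164% ± 0.0388, from 5, 6 and 4 reads, giving log2 differences of 12.01, 11.03 and 10.24 (adjusted p = 3.44e-07, 1.72e-05 and 5.55e-06). Adults held 34.4% ± 12.7 at X:9949531+ and 5.65% ± 7.54 at X:13655200+, against 0.550% ± 0.767 and 0.0474% ± 0.0446 in larvae (log2 -5.70 and -5.90). A further adult site, 2L:14617422+, took 0.318% ± 0.102, against 1 read in larvae. The model called 28 of 1241 sites, 13 higher and 15 lower in larvae, and 1 of 19 calls (5.26%) was false in simulated data for this comparison, over 1241 sites. Other settings called 7 (no filter) to 229 (limma voom with a depth-scaled prior), with 10 under lane terms. Both larval libraries were sequenced in lane 3, and with lane terms X:9949531+ stood at log2 -3.98 ± 1.17 (SE, adjusted p = 0.229), against -5.70 ± 0.99 before, and 2L:14617422+ at -4.87 ± 1.54 (adjusted p = 0.0604), against -5.51 ± 1.40. Both calls were lost, with a smaller fold and a wider error. Limma voom called 36 higher and 89 lower in larvae, 28.8% higher against 46.4%. The count was 5 without larva replicate 2, 9 without larva replicate 1 and 16 without adult day 1 replicate 2. The adult day 20 replicate 2 library, with 3295 reads, held 9.74% at X:9949531+ and 20.8% at X:13655200+, apart from the other 5 adult libraries. Between adult days 20 and 1 the model called 0 of 1241 sites, with 89 at an unadjusted p under 0.05, and limma voom called 20, limma voom with a depth-scaled prior 170 and limma trend 44. No call was made in simulated data for that comparison, over 1241 sites, so 4-fold changes would have been missed.

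Fat was followed from larvae to white prepupae and on to pupae. From prepupae to pupae 3R:2126460+ and X:1077409+ rose from 0 reads to 1.93% ± 0.464 and 1.10% ± 0.744 (n = 2), at least 135-fold and 77.2-fold (adjusted p = 0.0116 and 0.0220), and 3L:9827449+ rose from 1 read to 1.26% ± 0.440. Over the same days 3L:14087778- fell from 5.63% ± 0.859 (n = 2) to 0.0147% ± 0.0208 (log2 -7.15, adjusted p = 0.00897). There was also a fall at 2L:10462472+, from 0.395% ± 0.167 to 0 reads, a bound of 171-fold, with a smaller fold in the model (log2 -5.71). The site 3L:16720388+, which led in prepupal salivary glands, fell in fat from 0.395% ± 0.146 to 1 read. The model called 84 of 1241 sites, 47 higher and 37 lower in pupae, whereas TMMwsp scaling called 36 higher and 89 lower, 28.8% higher against 56.0%, limma voom 160 and 223 (41.8%), and limma trend 185 and 69 (72.8%). The pupal libraries held 37694 and 122588 reads and the prepupal ones 7499 and 15858. Reads from mate 1 of a read pair made up 37.9% and 56.6% in pupae, against 2.19% and 3.93% in prepupae. Median read lengths were 48 and 62 nt in pupae, against 64 and 89 nt in prepupae. Stage cannot be told apart from these differences between the libraries. In simulated data for this comparison, over 1241 sites, 2 of 11 calls (18.2%) were false. Other settings called 21 (larger flow cell alone) to 383 (limma voom), and the count was 1 without pupa replicate 2, 44 without pupa replicate 1, and 9 or 10 without prepupa replicate 1 or 2. From larvae to prepupae the model called 0 of 1241 sites in fat, with 74 at an unadjusted p under 0.05, and lane terms called 1, limma voom 31, limma voom with a depth-scaled prior 143 and limma trend 59. The model recovered 0.25% of sites changed 4-fold in simulated data for larvae against prepupae, so most changes of that size would have been missed.

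In salivary glands the white prepupa was compared with the larva. In prepupae 3L:16720388+ took 37.6% ± 11.3 (n = 2) of the reads, against 2.47% ± 0.400 (n = 2) in larvae (log2 4.81, adjusted p = 0.0448). Prepupae also held 8.33% ± 4.97 at 3L:15644578-, 3.23% ± 1.73 at 3L:15646196+ and 3.83% ± 2.18 at X:5396603+, against 0.183% ± 0.0674, 0.0183% ± 0.0143 and 0.132% ± 0.0460 in larvae (log2 5.94, 7.47 and 5.83). Larvae held 17.2% ± 3.20 at 3L:11506495+, 5.17% ± 1.59 at 3R:13420779+ and 3.31% ± 0.141 at 2L:3174442+, against 0.103% ± 0.0622, 0.0398% ± 0.00605 and 0.0159% ± 0.0191 in prepupae (log2 -6.26, -6.09 and -7.46). The model called 10 of 1241 sites, 7 higher and 3 lower in prepupae, and 0 when larva replicate 1, larva replicate 2 or prepupa replicate 2 was left out. Other settings called 0 (no filter) to 91 (limma voom with a depth-scaled prior), with 6 under lane terms. With these, 3L:16720388+ stood at log2 4.22 ± 1.12 (SE, adjusted p = 0.163), against 4.81 ± 1.00 before, X:5396603+ at 4.66 ± 1.05, against 5.83 ± 0.97, and 2L:3174442+ at -6.68 ± 1.38, against -7.46 ± 1.21 (adjusted p = 0.0594 each). These 3 calls were lost, with smaller folds and wider errors. On the larger flow cell alone 10 were higher and 21 lower (32.3% higher against 70.0%), and with only the compared groups 13 and 27 (32.5%). No call was made in simulated data for this comparison, over 1241 sites. Whether the change from larva to prepupa differed between salivary glands and fat was tested as an interaction, which called 0 of 1241 sites, with 78 at an unadjusted p under 0.05. Limma voom called 39, limma voom with a depth-scaled prior 135 and limma trend 68. With groups on 1 side of this interaction changed 4-fold in simulated data, the model recovered 5.25% of changed sites, so most would have been missed.

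In the CNS, pupae were compared with larvae. The model called 0 of 1241 sites, with 103 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0576. It recovered 0.25% of sites changed 4-fold in simulated data for this comparison, so most changes of that size would have been missed. TMMwsp scaling called 4 sites, the larger flow cell alone 3, only the compared groups 7, lane terms 3, PCR copies counted once 9, Pearson dispersions 9 and no flow cell term 11, while limma voom called 50, limma voom with a depth-scaled prior 41 and limma trend 59. The sites that led in the CNS as a whole are given with those of the other tissues.

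Each tissue was then set against the other 9, the model giving every tissue the same weight on the log scale. For these comparisons single libraries of the 2 sides were allowed to overlap at a named site. In heads 3R:15712031- took 0.622% ± 0.512 (n = 18), against 0.00103% ± 0.00415 (n = 40) in the other libraries (log2 6.02), and X:20292006+ took 0.578% ± 0.582, against 0.0158% ± 0.0368 (log2 5.49). X:9949531+ took 30.7% ± 24.5 of head reads and on average 5.71% of the others (log2 5.58). It also led in carcass, with 25.9% ± 19.0 (n = 8) against 11.5% ± 20.5 (n = 50), followed by X:13655200+, with 4.25% ± 6.88 against 1.32% ± 4.09, and 3L:9827449+, with 1.92% ± 1.18 against 0.336% ± 0.415 (log2 6.40, 5.58 and 4.99). In the CNS 3L:11726688- took 0.989% ± 0.369 (n = 4), 2R:4021874- 0.612% ± 0.350 and 3L:22782337- 0.574% ± 0.190, against 0.0445% ± 0.0733, 0.0168% ± 0.0317 and 0.0179% ± 0.0318 in the other 54 libraries (log2 5.41, 4.50 and 5.12). The model called 168 sites higher in heads, 172 in the CNS and 97 in carcass than in the other tissues. The head count was 85 without mated male day 20 replicate 2, the CNS count 109 without larva replicate 1, and the carcass count 41 without larva replicate 1 and 55 without adult day 20 replicate 1. On the larger flow cell alone 108 sites passed in the CNS and 45 in carcass, limma voom called 300 in heads and 175 in carcass, and lane terms 103 in heads, 83 in the CNS and 99 in carcass. In simulated data, over 1241 sites, 5.60% of the calls for heads were false. For this share and those of the tissues below, unchanged sites had the same mean in all tissues, unlike the real ones.

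The reproductive organs were set against the other tissues in the same way. Accessory glands, which make the proteins of the seminal fluid, held 15.5% ± 1.06 (n = 2) of their reads at 3R:21656441-, 6.58% ± 0.648 at 3L:16748820+ and 4.17% ± 2.61 at 3R:21657316-, against 0.0572% ± 0.274, 0.0478% ± 0.248 and 0.0289% ± 0.142 in the other 56 libraries (log2 10.75, 9.75 and 9.64). In testes 3L:10633240+, 3R:3190881- and 2L:18009694+ were 7.92, 7.09 and 6.72 higher on the log2 scale than in the other tissues, where 2L:18009694+ had 1154 reads, more than in testes. In ovaries 2L:5959699- took 7.30% ± 4.34 (n = 4), against 0.124% ± 0.269 in the other 54 libraries (2348 and 1867 reads, log2 7.72), 2L:5957628+ 1.41% ± 0.988, against 0.0118% ± 0.0267 (log2 6.55), and 2L:6926046+ 0.449% ± 0.0735, against 0.00406% ± 0.0114 (log2 4.60). The model called 281 sites higher in accessory glands, 252 in testes and 116 in ovaries. In simulated data, over 1241 sites, 10.5% of the calls for accessory glands and 5.11% for ovaries were false. TMMwsp scaling called 158 sites in accessory glands and 193 in ovaries, and lane terms 91 in accessory glands, 37 in testes and 6 in ovaries. The counts were 168 and 131 without accessory gland replicates 1 and 2, 163 and 153 without testis replicates 1 and 2, 74 and 75 without virgin ovary replicates 1 and 2, and 57 and 72 without mated ovary replicates 1 and 2.

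Among the remaining tissues, the digestive system held 4.40% ± 4.35 (n = 8) at 3R:17583484+, 2.93% ± 1.19 at 3L:6033235+ and 2.39% ± 0.360 at 3R:26315617+, against 0.0202% ± 0.0512, 0.0422% ± 0.0994 and 0.0218% ± 0.0724 in the other 50 libraries (log2 6.98, 6.95 and 7.03). Salivary glands held 20.0% ± 21.3 (n = 4) at 3L:16720388+, 4.26% ± 5.51 at 3L:15644578- and 3.98% ± 4.12 at 3R:13422639+, against 0.0305% ± 0.0931, 0.00753% ± 0.0249 and 0.0251% ± 0.116 elsewhere (log2 9.75, 7.04 and 7.25). Fat held 15.7% ± 12.1 (n = 6) at 3L:12124796+, 6.05% ± 3.59 at 3R:25541975- and 2.88% ± 3.95 at 3L:68995+, against 0.308% ± 0.469, 0.0654% ± 0.149 and 0.0156% ± 0.0283 elsewhere (log2 7.21, 7.76 and 6.03). In imaginal discs 3R:14519005- took 0.767% ± 0.752 (n = 2), against a mean of 0.170% ± 0.808 over the other 56 libraries, most of it from larval digestive systems (log2 5.76). The model called 208 sites higher in the digestive system, 68 in salivary glands, 87 in fat and 268 in imaginal discs. In simulated data, over 1241 sites, 6.89% of the calls for the digestive system and 7.87% for salivary glands were false. The larger flow cell alone gave 135 sites in the digestive system and 175 in imaginal discs, and lane terms 155 in the digestive system, 106 in imaginal discs, 21 in salivary glands and 48 in fat. In 13 of the 30 tests of the 3 sites with the largest fold in each tissue, lane terms decided nothing, since libraries with 0 reads left lane and tissue inseparable. The counts were 144 and 113 without imaginal disc replicates 1 and 2, 36 without salivary gland larva replicate 1, 27 without salivary gland prepupa replicate 2, and 49, 57 and 56 without replicate 2 of larval, prepupal and pupal fat.

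**Figure D2:**
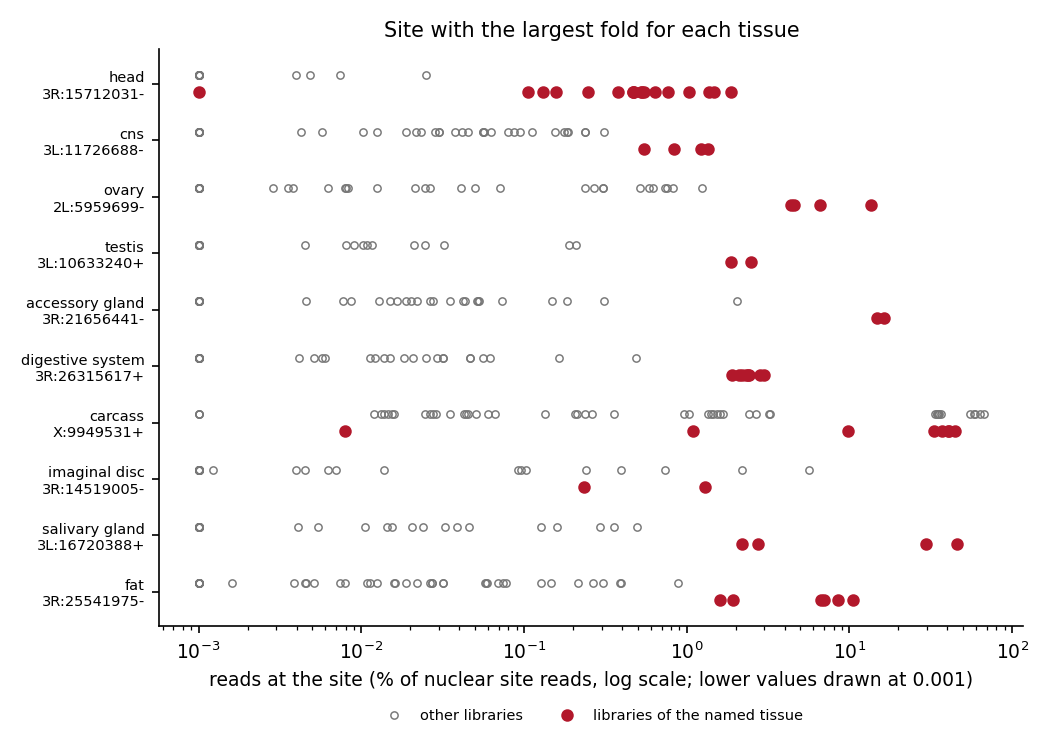
Reads at the site with the largest fold for each tissue, as a percent of nuclear site reads on a log axis, in the libraries of that tissue (filled points) and in all other libraries (open points). Values below 0.001%, including 0, are drawn at 0.001; in carcass the leading site X:9949531+ is shared with female heads.

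The study mapped poly(A) sites to find transcripts with more than 1 end, and 787 runs of neighbouring sites on a strand held at least 2 sites in regular use. In each, the reads at the most downstream site were compared with all reads of the run between a tissue and the other tissues. Runs were formed by distance, so a run may span neighbouring genes. Where a run is named, its position is that of the distal site, and levels are distal shares over pooled reads of the libraries counted. Of 81 runs called over all tissues, 22 had only 1 library with enough reads in 1 of the arms, and no such run is named. In heads, at X:17177794-, 0% of 56 reads and 52.9% of 923 other reads were distal (adjusted p = 0.00377). In the digestive system 0% of 25 reads and 92.2% of 115 other reads were distal at 2R:19834476- (adjusted p = 5.75e-08). Salivary glands used the distal site of 2R:10402859+, 362 nt from the proximal one, in 55.0% of 40 reads, against 0.301% of 332 reads elsewhere (adjusted p = 4.66e-08), though the 2 gland libraries differed widely (36.7% ± 51.9). Fat used the distal site of 3L:21980295+, 152 nt from the proximal one, in 3.97% of 428 reads, against 78.1% of 210 (adjusted p = 0.0413). Carcass used the distal site of 3R:4173380+ in 58.3% of 24 reads, against 0.952% of 105 (adjusted p = 3.92e-05), and ovaries that of X:1238803+, 204 nt from the proximal one, in 20.8% of 24 reads, against 87.9% of 521 (adjusted p = 0.0288). The 1 run called in accessory glands, 2R:8306638-, had 98 of 98 reads at the distal site there, and in the digestive system 0 of 20.

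Counting more distal and more proximal runs, the quasi-binomial model called 13 and 11 of 276 in heads, 12 and 11 of 322 in the digestive system, 10 and 12 of 279 in fat, 5 and 2 of 114 in salivary glands, 0 and 3 of 75 in ovaries, 1 and 0 of 86 in accessory glands and 1 and 0 of 207 in carcass. It called 0 of 148 runs in the CNS, 0 of 64 in testes and 0 of 49 in imaginal discs, with 20, 9 and 3 at an unadjusted p under 0.05, where limma on log2 odds called 3, 2 and 0. In simulated runs of all tissues together 8.09% of 235 calls were false and 34.2% of changed runs were recovered. These runs pooled correlations between reads below and above the fitted ones, so the shares hold for no single correlation. A stricter version, with the larger of both dispersions, gave 13 false of 196 (6.63%) and recovered 29.0%. The salivary gland count was 0 without prepupa replicate 2, the ovary count 0 or 1 without any 1 of the 4 ovary libraries, the accessory gland count 0 without replicate 1, and the CNS count 2 without pupa replicate 2. The carcass count was 0 with PCR copies counted once, on the larger flow cell alone and with limma on log2 odds. Limma on log2 odds also called only 3 runs in heads and 0 in salivary glands, and with PCR copies counted once 1 was left in salivary glands.

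Averaged over runs, the CNS used distal sites more than the other tissues. Its distal score, the mean over runs of the distal share minus the run's average over tissues, was 6.04 ± 2.01 percentage points (n = 4), against -0.480 ± 3.53 (n = 54) in the other libraries, and lay above 3.74 in all 4 (two-sided exact permutation p = 0.000580, adjusted p = 0.00580 over 10 tissues). On the larger flow cell alone the difference was 6.82 points (exact permutation, n = 3, adjusted p = 0.0105). Without CNS larva replicate 2 it was 5.67, and the adjusted p was 0.0690, and with at least 20 reads per run in a library it was 5.83, and the adjusted p was 0.517. Testes followed, 4.43 points above the rest (exact permutation, n = 2, adjusted p = 0.378). The other 8 tissues lay between 2.32 points below and 1.82 above the rest, with adjusted p of 0.378 to 0.769 by permutation. Carcass, 2.32 points below, differed by -4.78 points with at least 20 reads per run, with the smallest p of any tissue under that setting (permutation p = 0.00556, adjusted p = 0.0556). The sign of the difference changed for heads on the larger flow cell alone (-0.676), for accessory glands at 20 reads per run (-0.711) and without accessory gland replicate 2 (-0.589), and for salivary glands without prepupa replicate 1 (0.0328).

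**Figure D3:**
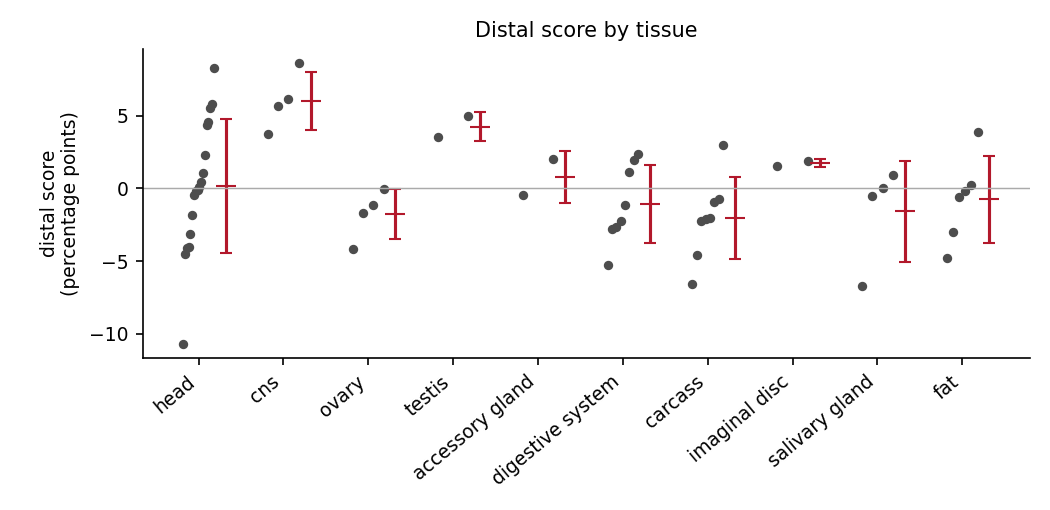
Distal score of each library in percentage points, by tissue. Points are libraries and red bars are means ± SD; the 4 CNS libraries lie between 3.74 and 8.62.

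Reads on the mitochondrial genome made up 3.18% ± 2.72 (n = 6) of all reads in fat and 2.25% ± 1.36 (n = 8) in the digestive system, and 0.254% ± 0.142 (n = 4) in ovaries and 0.262% ± 0.131 (n = 2) in imaginal discs. No tissue passed after adjustment over 10 tissues. The smallest values came from fat, 1.93 points above the other libraries (permutation p = 0.0127, adjusted p = 0.110), and from ovaries, with a difference of -1.28 points (two-sided exact permutation p = 0.0220, adjusted p = 0.110). Pupal fat libraries held 6.58% and 6.42%, and those of larvae and prepupae 0.511% to 2.54%, so the mean of fat depended on the pupal ones. With PCR copies counted once, the shares were 0.725% ± 0.374 in fat and 0.530% ± 0.191 in the digestive system, and fat lay 0.265 points above the other libraries (permutation, adjusted p = 0.165). Ovaries then had the smallest p, with a difference of -0.264 points (exact permutation p = 0.0118, adjusted p = 0.118).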

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

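The flagging rule was fixed before the data were examined, and the tests of the 3 patterns below were chosen after the results were seen. The rule asked whether 1 library of a group of 4 to 10 stood apart from the others by a large part of the group's range. It picked out 11 of 49 groups of values (22.4%), where its limits are set so that chance flags about 1 in 20 independent groups. The groups here overlap and share libraries, so the 2 shares are not a test. Mated female head day 20 replicate 2 held 26.2% of its reads at X:13655200+, against at most 3.74% in the other 5 mated female heads, and 2.03% at X:9945057-, against at most 0.933%. All 4 day 20 female heads lay above the 8 younger ones at both sites. Adult carcass day 20 replicate 2, a library of 3295 reads, held 20.8% at X:13655200+ (next 5.38%), which stood apart among the 6 adult libraries and again among all 8, and 9.74% at X:9949531+, where the next lowest adult library held 33.1%. The same library was highest of the adults at the larval sites 2R:4325738+ (0.0955%), 2R:4318143- (0.159%) and 2R:4321478- (0.0955%). Virgin ovary replicate 2 held 0.339% at 2L:6926046+, where the next lowest ovary library held 0.481%. Digestive larva replicate 2 held 5.60% at 3L:6033235+ (next 3.20%), and adult digestive day 4 replicate 1 was the only adult digestive library with reads at 3R:14519005- (0.00452%).

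Accessory glands used 26 sites far above other tissues, and testis libraries held reads at most of them. Testis replicate 1 held 1020 reads (6.83%) over 20 of these sites and replicate 2 held 227 (2.42%) over 21. The 5 head libraries of the same lane held at most 10 reads at these sites and 1 of them 0. The sites were picked as at least 100-fold lower in all libraries other than accessory glands, testes and adult parts of mixed sex. Low head values were thus partly built in and cannot decide on a leak spread evenly over the lane. Other libraries of the lane, which this limit did not cover, held more: adult digestive day 4 replicates 1 and 2 held 129 and 165 (0.291% and 0.265%), adult carcass day 4 replicate 2 held 42 (0.113%) and adult digestive day 20 replicate 1 held 28 (0.118%). A leak within the lane, or tissue carried over into these parts of mixed sex, could give such values, so reads given to a wrong library could not be excluded. If accessory gland tissue had been carried over, the sites would stand in the ratios they have there. The spread of the ratios was 1.88 and 0.943 times that between the accessory gland libraries, within the limit of 2. It was taken over 18 and 9 sites with at least 5 expected reads in testes, but over all 26 between accessory glands. Unlike sets of sites can shift the ratio, so carry-over met the limit but was not settled. Use of these sites by testes themselves was not tested and was not excluded.

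Male heads held X:9949531+ at 0.581% ± 0.645 (n = 6). In 1 lane 3 male head libraries held 2 to 207 reads, a 103.5-fold range, which excluded an even leak of reads from the female libraries of the lane, though an uneven one stayed open, as did any leak in the other lanes, which held 1 male head each. Female tissue carried over could not be told apart from use by males: X:13655200+ stood at 9.16% of X:9949531+ on average in the 2 male day 4 libraries, above the 3.69% to 4.61% of female heads of that day, but from 13 reads in each.

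Larval CNS libraries held reads at sites of larval carcass, at 5 of 5 in replicate 1 and 4 in replicate 2. Replicate 1, in a lane with no larval carcass library, held 2.24% of its reads there, which excluded reads from a wrong library of the lane for that library. Replicate 2 held 2.41% and shared its lane with both larval carcass libraries, so for it they could not be excluded. The spread of the site ratios, over 3 sites in each CNS library, was 5.57 and 1.22 times that between the larval carcass libraries over all 5. Carry-over of carcass tissue could thus not be decided. No biological explanation was tested for this pattern.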

How the results depend on the processing

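The alternatives with limma tests of sites, Pearson dispersions, reads weighed in full, the larger flow cell alone, lane terms and no shallow libraries were chosen after the data were seen. Sites and runs picked by the naming rule were not followed under the limma tests, and none changed direction under the alternatives in which they were followed. They were picked from the same data for large differences past the threshold, so a stable direction was largely built in. In direct comparisons of sites, every library of 1 arm also lay above every library of the other. Of 65 tests on the 47 sites picked by the naming rule for the text, 20 lost the threshold with no filter, 1 with TMMwsp scaling and none with Pearson dispersions, mitochondrial reads kept or the shallow libraries left out. With lane terms 19 of 65 lost it, and at 13 of the 19 libraries with 0 reads left lane and group free to trade against each other, so the test there says nothing. The same held for 2 of those that kept it. The other 6 were weaker. Over all libraries left out, 56 tests of a named site or run lost the threshold and 1935 kept it. Most of these refits were of the 30 tissue tests, for each of which all 58 libraries were left out in turn, mostly libraries of other tissues. The share kept therefore says little about the direct comparisons, several of whose counts fell far more, as given below. Mitochondrial reads kept changed none of 25 counts by over 1.5 times. TMMwsp scaling moved the median log2 over all sites by -0.445 (accessory gland) to 0.155 (head), so small shifts depend on the scaling. In simulated data 4-fold changes were recovered in 0.25% of cases for ovaries and 0.875% for day 20 against day 1 of the digestive system, with 2 libraries per arm, and in 18.5% for the ageing of heads, with 6 per arm; depth and number of libraries were not told apart. No paired analysis was possible because the replicate numbers are only the order of deposit and pair no libraries. Lanes were shared across groups and entered as terms only. DESeq2 on reads per gene, no downstream window, the filter on internal priming, and the AATAAA share by its unit, smallest site and window were not run, for lack of a counts column or of a genome and annotation of dm3 used here.

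Counts of sites or runs that moved by over 1.5 times, and values that lost the threshold or changed sign, were as follows, where a tissue alone stands for sites higher in it. A distal score or mitochondrial share in this list is the difference between the tissue and the other libraries, in percentage points. The cause was not tested for any of them. With no filter, head male against mated female gave 3, head day 20 against day 1 3, testis against ovary 15, digestive larva against adult 6, carcass larva against adult 7 and fat pupa against prepupa 26. Salivary gland prepupa against larva gave 0, digestive 358 and carcass 64. With PCR copies counted once, head male against mated female gave 11, head day 20 against day 1 16, testis against ovary 85, carcass larva against adult 97, fat prepupa against larva 8 and fat pupa against prepupa 54. Salivary gland prepupa against larva gave 33, CNS pupa against larva 9, CNS 74, ovary 41, testis 97 and accessory gland 107. Digestive gave 95, imaginal disc 106, CNS distal runs 4, testis distal runs 4, carcass distal runs 0 and salivary gland distal runs 1. Fat distal runs gave 7, CNS mitochondrial share 0.0218 and salivary gland mitochondrial share 0.0276. With Pearson dispersions, head male against mated female gave 17, head day 20 against day 1 48, testis against ovary 262, digestive larva against adult 215, carcass larva against adult 123 and fat prepupa against larva 5. Fat pupa against prepupa gave 282, salivary gland prepupa against larva 76 and CNS pupa against larva 9. With only the compared groups, head male against mated female gave 12, head day 20 against day 1 36, digestive larva against adult 234, digestive day 20 against day 1 129, carcass larva against adult 10, fat prepupa against larva 12, salivary gland prepupa against larva 40 and CNS pupa against larva 7. Under limma voom, head male against mated female gave 20, head mated against virgin female 3, head day 20 against day 1 68, testis against ovary 257, digestive larva against adult 232 and digestive day 20 against day 1 11. Carcass larva against adult gave 125, carcass day 20 against day 1 20, fat prepupa against larva 31, fat pupa against prepupa 383, salivary gland prepupa against larva 65 and CNS pupa against larva 50. Head gave 300, accessory gland 146, carcass 175, imaginal disc 120, fat 174 and prepupal change fat against salivary gland 39. Under limma voom with a depth-scaled prior, head male against mated female gave 35, head mated against virgin female 9, head day 20 against day 1 99, ovary mated against virgin 3, testis against ovary 359 and digestive larva against adult 181. Digestive day 20 against day 1 gave 14, carcass larva against adult 229, carcass day 20 against day 1 170, fat prepupa against larva 143, fat pupa against prepupa 217 and salivary gland prepupa against larva 91. CNS pupa against larva gave 41, head 254, accessory gland 119, carcass 156, imaginal disc 148, fat 172, head sex by age interaction 31 and prepupal change fat against salivary gland 135. Under limma trend, head male against mated female gave 24, head mated against virgin female 4, head day 20 against day 1 103, ovary mated against virgin 3, testis against ovary 303 and digestive larva against adult 203. Digestive day 20 against day 1 gave 26, carcass larva against adult 158, carcass day 20 against day 1 44, fat prepupa against larva 59, fat pupa against prepupa 254 and salivary gland prepupa against larva 64. CNS pupa against larva gave 59, accessory gland 157, carcass 163, fat 172, head sex by age interaction 12 and prepupal change fat against salivary gland 68. With TMMwsp scaling, head day 20 against day 1 gave 14, CNS pupa against larva 4, ovary 193 and accessory gland 158. Without a flow cell term, head day 20 against day 1 gave 14, carcass larva against adult 54, fat prepupa against larva 4, salivary gland prepupa against larva 27, CNS pupa against larva 11, testis distal runs 2 and fat distal runs 14. On the larger flow cell alone, head day 20 against day 1 gave 10, digestive larva against adult 24, fat pupa against prepupa 21, salivary gland prepupa against larva 31, CNS pupa against larva 3 and CNS 108. Accessory gland gave 170, digestive 135, carcass 45, imaginal disc 175, accessory gland distal runs 0, carcass distal runs 0, head distal score -0.676 and CNS mitochondrial share 0.270. With lane terms, head day 20 against day 1 gave 0, testis against ovary 19, digestive larva against adult 43, carcass larva against adult 10, fat prepupa against larva 1 and salivary gland prepupa against larva 6. CNS pupa against larva gave 3, head 103, CNS 83, ovary 6, testis 37 and accessory gland 91. Imaginal disc gave 106, salivary gland 21 and fat 48. Without the shallow libraries, testis against ovary gave 67. With limma on log2 odds, head distal runs gave 3, CNS distal runs 3, testis distal runs 2, accessory gland distal runs 3, digestive distal runs 13, carcass distal runs 0 and salivary gland distal runs 0. With sites joined within 10 nt, CNS distal runs gave 4, ovary distal runs 1 and testis distal runs 4. With sites joined within 50 nt, CNS distal runs gave 2 and accessory gland distal runs 2. With a smallest share of 10%, CNS distal runs gave 4, testis distal runs 4, carcass distal runs 2 and fat distal runs 13. With reads weighed in full, CNS distal runs gave 12, testis distal runs 4, accessory gland distal runs 9, digestive distal runs 63, carcass distal runs 5, salivary gland distal runs 24 and fat distal runs 127. With at least 20 reads per run, the difference in distal score from the other libraries was 5.83 for CNS and -0.711 for accessory gland.

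Leaving out each library in turn gave ranges of head male against mated female 3 to 6, head day 20 against day 1 0 to 10, testis against ovary 14 to 93, digestive larva against adult 3 to 67, carcass larva against adult 5 to 39 and fat pupa against prepupa 1 to 44. Salivary gland prepupa against larva 0 to 8, head 85 to 185, CNS 109 to 199, ovary 57 to 116, testis 153 to 260 and accessory gland 131 to 283. Digestive 155 to 247, carcass 41 to 134, imaginal disc 113 to 297, salivary gland 27 to 92, fat 49 to 99 and CNS distal runs 0 to 2. Ovary distal runs 0 to 1, accessory gland distal runs 0 to 1, salivary gland distal runs 0 to 8, CNS distal score 5.67 to 7.15, ovary distal score -2.12 to -1.37 and testis distal score 4.94 to 5.77. Accessory gland distal score -0.589 to 2.23, imaginal disc distal score 1.23 to 1.91, salivary gland distal score -2.55 to 0.0328, CNS mitochondrial share -0.544 to 0.0216, ovary mitochondrial share -1.32 to -1.22 and testis mitochondrial share -0.842 to -0.638. Accessory gland mitochondrial share -1.31 to -0.619, imaginal disc mitochondrial share -1.32 to -1.13 and salivary gland mitochondrial share -1.18 to -0.811. Distal scores and mitochondrial shares in these ranges are differences from the other libraries, in percentage points. For these values and for distal runs, no library of heads, digestive system, carcass or fat was left out. The count stayed at 0 for head mated against virgin female, ovary mated against virgin, digestive day 20 against day 1, carcass day 20 against day 1, fat prepupa against larva, CNS pupa against larva, head sex by age interaction, prepupal change fat against salivary gland, testis distal runs and imaginal disc distal runs.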

Other observations

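The tests in this part were written before their results were seen, except those under other settings, which were chosen afterwards. Sites higher in larvae than in adults were shared by the digestive system and the carcass at 3 sites (0.513 expected, p = 0.0125 by Fisher's exact test, one-sided here and for the shared sites below), namely 2R:4325738+, 3R:2525281- and 3R:14519005-. Sites higher in adults were shared at 9 (0.459 expected, exact p = 3.84e-11), namely X:9949531+, X:13655200+, X:9945057-, 2L:5959699-, 2L:14617422+, 2L:3696239-, 2R:19915041+, 3R:9144714- and X:21273407-. The 3 leading female head sites were thus among the adult sites of both tissues, whose adults were of mixed sex. Tissue carried over between the dissected parts would also give shared sites and was not tested. Both larval carcass libraries and 1 of the 2 larval digestive ones shared lane 3. The same test with lane terms gave 1 shared larval site (exact p = 0.0706) and 2 shared adult sites (exact p = 0.00376), 2L:3696239- and X:13655200+. The larger flow cell alone gave 1 (exact p = 0.171) and 0 (exact p = 1.00), TMMwsp 5 and 8, and PCR copies counted once 13 and 18.

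Sites higher in 1 tissue lay near one another in the genome in 5 of 10 tissues. Counting sites with a neighbour of the same list more than 2000 nt and up to 20 kb away, ovaries had 21 (7.34 in 10000 random lists, adjusted p = 0.00800), imaginal discs 59 (37.0, adjusted p = 0.00867), salivary glands 12 (2.56, adjusted p = 0.00867), carcass 14 (5.20, adjusted p = 0.0210) and the digestive system 38 (22.9, adjusted p = 0.0250). Random lists were not matched on level, and far sites of a long gene count as neighbours. The number of tissues past 0.05 depended on the lists: 2 with TMMwsp, 4 with PCR copies counted once, 5 on the larger flow cell alone and 0 with lane terms, whose lists are shorter in 9 of 10 tissues. The X chromosome held fewer of the sites of 1 of 10 tissues than of the rest: 10.3% in accessory glands against 20.4% of other sites (Fisher's exact test, adjusted p = 0.000682). Salivary glands, with 7.35% against 18.8%, and imaginal discs, with 13.1% against 19.5%, had an adjusted p of 0.0516 each, and testes, with 13.1% against 19.4%, one of 0.0545. The share in accessory glands was 8.23% with TMMwsp (158 sites, adjusted p = 0.00354) and 10.6% on the larger flow cell alone (170 sites, adjusted p = 0.0181). It was 10.3% against 17.0% with PCR copies counted once (107 sites, adjusted p = 0.240) and 17.6% against 18.2% with lane terms (91 sites, adjusted p = 1.00), so the deficit was not settled.

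Other splits of the libraries, 100 for each result with the real one among them, were set against the real counts. A split mostly put unlike libraries into the same group, which can widen the fitted spread and lower its calls. Few splits as large therefore do not exclude chance, and the results were not adjusted for their number. Nor do they exclude an effect of the lane, which in heads partly followed age (0 sites for day 20 against day 1 with lane terms). Fewer than 5 of 100 splits were as large for male against female heads (6 sites, 1 split as large, highest other 5) and day 20 against day 1 in heads (5, 2 splits, highest 12). The same held for the sites higher in heads (168, 1, highest 1), CNS (172, 1, highest 128), ovaries (116, 1, highest 108) and digestive system (208, 1, highest 46). It also held for those of carcass (97, 1, highest 32), salivary glands (68, 4, highest 121) and fat (87, 1, highest 66). Distal runs in heads (24, 1, highest 13), digestive system (23, 1, highest 21) and fat (22, 1, highest 19) likewise had fewer than 5. At least 5 splits were as large for distal runs in ovaries (3, 17, highest 13), carcass (1, 54, highest 22) and salivary glands (7, 5, highest 15), so these counts were not unusual among the splits. For mated against virgin heads (0, 100, highest 1) and CNS distal runs (0, 100, highest 21) the real count was 0, so all 100 splits were as large by construction and the test says nothing. Other splits called more than the real one for distal runs in ovaries (13 against 3), carcass (22 against 1) and salivary glands (15 against 7), for sites of salivary glands (121 against 68) and for day 20 heads (12 against 5). This may point to structure among the libraries that the groups do not follow, which was not tested.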
